A study of Homo sapiens with 20 samples.

How the data were processed

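RNA from human neutrophils of 5 healthy donors was sequenced in 4 groups of 5 libraries: unstimulated cells with vehicle, and cells given lipopolysaccharide (LPS) after vehicle, a TPL2 inhibitor or a MEK inhibitor. Per the labels' protocols, neutrophils were isolated from whole blood by negative selection to a purity of at least 99% by flow cytometry, and were held in medium with 0.5% serum. Vehicle (0.5% DMSO) or inhibitor was given for at least 30 min before 10 ng/ml LPS, which stayed on for 6 h, and unstimulated cells received vehicle for 6.5 h. Libraries were made from polyadenylated RNA with a TruSeq v2 kit, which does not mark the strand, and were sequenced on a HiSeq 2500 as single-end reads of 50 bases. The inhibitors are named here by their target, since their doses and structures are not given in the sources used here.

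The deposited files hold, for each library, a whole-number count of reads per gene and an RPKM value per gene. GSNAP, DESeq2 and the genome build GRCh37 are named per the submitters' processing notes, without versions or the step each was used for. The program that turned alignments into counts and the gene annotation are not given in the sources used here. The deposited counts were used as they stand. The deposited RPKM values, scaled by the authors to the gene width in each file and to a library total of 1.06 to 1.14 times the summed gene counts, were used only to check the files. Each file lists 26468 genes by NCBI Gene ID, of which 24519 matched a symbol in the RefSeq gene table of GRCh38.p14, used for names only. The 1949 genes without a match, at most 5.18% of the counts of a library, stayed in the tests and are not named. To protect the donors, 107 sex-linked genes were left out of every step. Counts were identical to those of another gene in all libraries for 265 genes, 200 of them tested. Genes with a near-identical copy, an overlapping gene or an antisense partner are uncertain where the counting could split or mix their reads (NCF1, CCL3, CCL4, HSPA1A, HSPA1B, FCGR3B, FAM86B3P, AMACR, IL6).

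The total count per library was between 22312929 and 42937297. The group means were 30621017 ± 6486333 (SD, n = 5) in unstimulated cells, 32163871 ± 6370911 with LPS, 29986891 ± 6458848 with the TPL2 inhibitor and 29324287 ± 2965643 with the MEK inhibitor. The 10 most abundant genes held 6.80%, 9.01%, 7.88% and 8.76% of the counts. No library pair looked like 1 library deposited more than once: over 190 pairs the smallest chi-square per degree of freedom was 10.8. The common dispersion was 0.0125, a biological coefficient of variation of 11.2%.

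Groups, tests, gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on all 20 libraries, with TMM scaling, edgeR's filter on low counts, and group and donor as terms, which left 12 residual degrees of freedom and 14677 tested genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. The donor block comes from the design text, which says that the cells of each donor were split over the groups. In a check of the pairing, deviations from the group mean of libraries with the same donor number correlated at r = 0.625 to 0.864 (median 0.765), those with different numbers at -0.469 to 0.0445, and in 60 of 60 cases a library matched its own number best. Since the block removes donor differences in level, p-values set each difference between groups against how far such differences vary from donor to donor. That variation is a single estimate per gene shared by all groups. For the inhibitor comparisons it therefore also holds the donor variation of the LPS response. Contrasts were LPS against unstimulated, each inhibitor with LPS against vehicle with LPS, and the TPL2 against the MEK inhibitor.

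In every comparison the text names the 5 largest called rises and falls with a mean log2 CPM of at least 3 and the same direction in 5 of 5 donors, without HLA, immunoglobulin, T cell receptor, LOC and LINC genes and genes with no symbol. It also names the 2 members of each response list with the smallest p, and MAP3K8, TNF, IL1B, IL6, CXCL8, CCL3, PTGS2 and DUSP6, in all 105 genes, of which 1 is not reported here. Other genes were chosen after their values were seen. These are CCL2, CXCL1, IL10, IL12B, IL15, TNFSF10 and TNFSF13B among cytokines, CD14, CXCR1, CXCR2, FOS, IER2, G0S2, HSPA5 and CYP51A1, and INSIG1, SOD2, NAMPT and SLC7A11 in some comparisons, together with the genes of the closing observations. Of each marker list the most abundant gene is named.

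The 14 response lists cover inflammatory cytokines and chemokines, NF-kB genes, ERK targets, interferon-stimulated genes, negative regulators, cAMP-CREB targets, the prostaglandin and leukotriene pathway, receptors, granule and NADPH oxidase genes, survival genes, glycolysis and hypoxia, TLR4, TPL2 and MAPK pathway components, stress responses and cholesterol metabolism. Marker lists, a family of their own, cover monocytes, eosinophils, T and NK cells, B cells, platelets, red cells, neutrophils, mitochondrial transcripts and ribosomal protein genes. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, which asks more of a list whose genes vary together, and fry. Adjustment ran over lists and comparisons, and members were also adjusted over the list alone.

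The share of the LPS response kept under an inhibitor is the median over genes of the log2 change with inhibitor and LPS over that with LPS alone, both against unstimulated cells. Genes were chosen at 2-fold in some donors and measured in the others, over all 20 splits into 2 and 3 donors, from log2 CPM with a prior count of 2. Because both inhibitor comparisons use the same LPS libraries, overlaps and correlations are given beside values from simulated unchanged groups, from independent lists and from splits that take the 2 comparisons from different donors. A class of genes was defined as called for the TPL2 inhibitor and, with the same sign, in the direct comparison, and not called for the MEK inhibitor.

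Alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone), no filter or a stricter filter on low counts (CPM of at least 1 in at least 5 libraries), DESeq2 1.42.0, limma-voom, no donor block, the 10 libraries of the groups compared, each donor left out in turn and a 2-fold minimum. A fit of the 15 libraries of the 3 LPS groups was added after seeing the data. The tests were tried on simulated counts with known changes at the real library sizes. For the recovery of changed genes, all groups were set to the gene levels of the LPS group with vehicle, with 1 dispersion per gene. The 3 comparisons thus had like settings, with 67 or 66 genes changed per fold, and differences between their recoveries do not rank them. At 1.5-fold, 2-fold and 4-fold, 71.6%, 94.0% and 100% of changed genes were recovered for the LPS comparison (14480 genes), 62.7%, 89.6% and 95.5% for the TPL2 inhibitor (14457 genes) and 80.6%, 89.6% and 97.0% for the MEK inhibitor (14468 genes). False calls made up 4.32%, 7.30% and 3.26% of calls. A simulated share kept of 50% came out as 49.5% and one of 100% as 100.07% (14677 genes). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.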

Results

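RNA was sequenced from human neutrophils, the most abundant white cells of blood and early responders to bacteria, taken from 5 healthy donors. The cells of each donor were divided over 4 groups, which gave 20 libraries with 5 per group. Cells of the unstimulated group received vehicle alone for 6.5 h. Those of the other groups received vehicle, an inhibitor of TPL2 or an inhibitor of MEK for 30 min and then 10 ng/ml lipopolysaccharide (LPS), a bacterial cell wall component sensed by TLR4, for 6 h. TPL2, the product of MAP3K8, is a kinase that activates MEK1 and MEK2, the kinases above ERK, and the study asked which part of the TPL2 response does not run through MEK. Gene counts summed to between 22312929 and 42937297 per library, with group means between 29324287 and 32163871, and 14677 genes were tested. Gene levels are given as mean CPM (counts scaled to library size) ± SD over n = 5 donors. Changes are log2 fold changes ± SE with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test, blocked by donor. The SE was derived from that test, as the size of the change over the square root of its F statistic.

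LPS switched on a broad inflammatory program in the neutrophil preparations. IL6 (NCBI Gene ID 3569) rose from 0.330 ± 0.292 to 132 ± 142 CPM, a log2 change of 8.58 ± 0.24 (adjusted p = 1.36e-13), although its level differed widely between donors. With LPS, donor 3 had the highest IL6 (379 CPM, others 43.7 to 126) and the highest summed monocyte markers (242 CPM, others 98.3 to 133). Among the others the order differed, with 126 and 103 CPM in donor 2 and 52.6 and 133 CPM in donor 1. Which cells the IL6 RNA came from was not tested. TNF (Gene ID 7124) rose from a low level to 299 ± 117 CPM (5.07 ± 0.14, adjusted p = 3.23e-14), and the genes of both IL-1 cytokines rose as well, IL1A by 8.07 and IL1B by 6.37 on the log2 scale. CXCL8, which encodes the neutrophil attractant IL-8, was already at 2819 ± 641 CPM without LPS and reached 17244 ± 2911 CPM (2.64 ± 0.12, adjusted p = 4.76e-12). MAP3K8 (Gene ID 1326), the gene of TPL2 itself, rose by 4.78 ± 0.14 to 1909 ± 452 CPM (adjusted p = 3.23e-14). Among the genes with mean log2 CPM of at least 3, the largest rises that held in all 5 donors were those of IL1A, CCL3, GPR84, IL1B and CCL20, between 6.33 and 8.07, and the largest falls were those of RNASE6 (-3.73), IMPA2 (-3.57), AMACR (-3.37), the AMACR readthrough gene (-3.26) and PHOSPHO1 (-3.21). The AMACR gene and its readthrough share exons, so their counts are uncertain, and CCL3 has a near-identical copy. IL6 overlaps an antisense gene, whose reads the library kit does not tell apart from those of IL6.

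**Figure D1:**
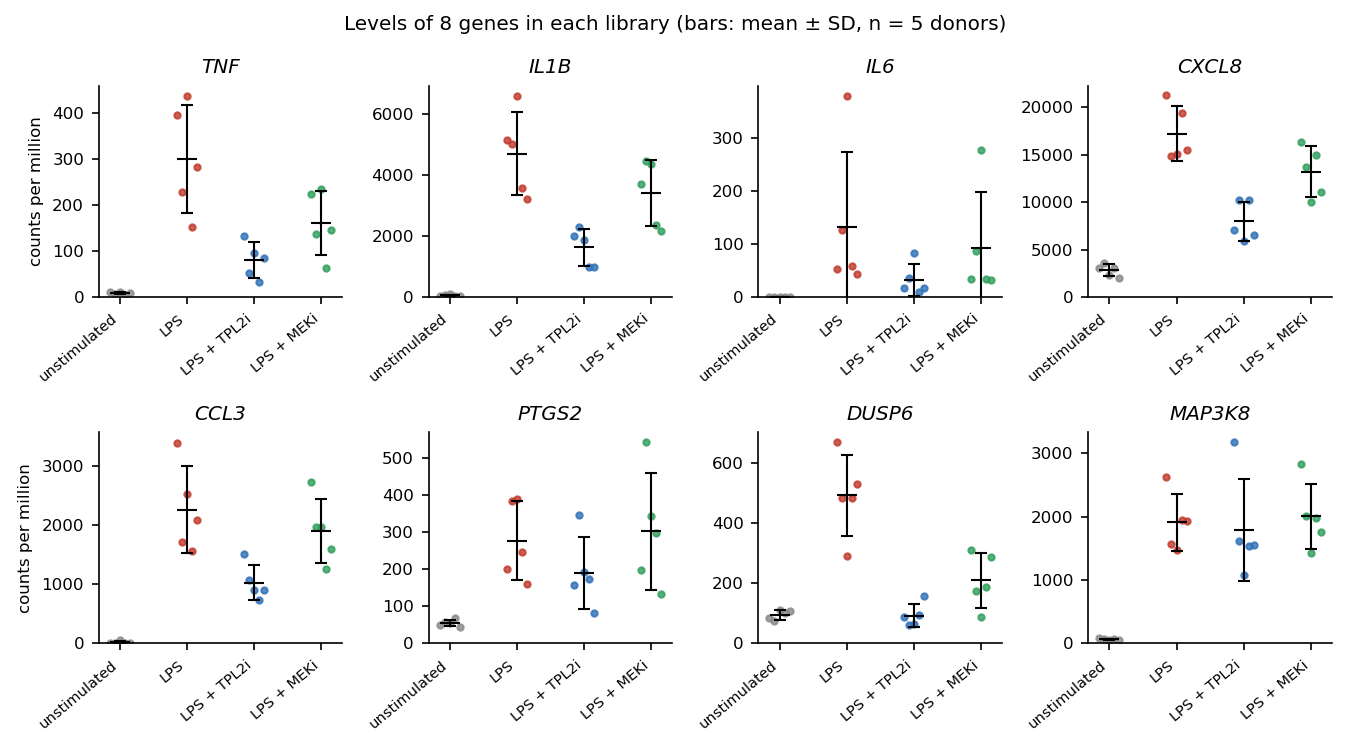
Level in CPM (linear axis) of TNF, IL1B, IL6, CXCL8, CCL3, PTGS2, DUSP6 and MAP3K8 in each of the 20 libraries, with 1 point per donor and bars for the mean ± SD (n = 5 donors per group). The mean of TNF is 299 with LPS, 79.3 with LPS and the TPL2 inhibitor and 161 with LPS and the MEK inhibitor, whereas the means of MAP3K8 lie between 1792 and 2004 in the 3 LPS groups.

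Of the 38 tested inflammatory cytokine and chemokine genes, 30 rose and 6 fell with LPS (31 and 6 when adjusted over the list alone; camera adjusted p = 5.58e-33), and their summed level went from 3486 ± 669 to 29775 ± 4606 CPM. IL36G, an IL-1 family cytokine gene, had a change of 8.11 ± 0.28, and the genes that fell included TNFSF13B and TNFSF10. Of 41 NF-kB feedback and target genes, 40 rose and 1 did not pass the test (40 over the list alone). NFKBIZ, which encodes an atypical IkB protein, rose by 5.30 ± 0.17 (adjusted p = 1.36e-13), and NFKB1 by 2.90. ERK pathway target and feedback genes moved mostly upward, with 22 of 35 higher and 7 lower (22 and 8 over the list alone). Among them MAFF rose by 3.32 and the ERK phosphatase gene DUSP6 from 95.5 ± 16.1 to 492 ± 135 CPM (2.30 ± 0.25, adjusted p = 1.62e-06), while FOS and IER2 fell. Anti-inflammatory and negative regulators also rose, 24 of 35 against 5 that fell (the same counts over the list alone), with IL1RN, the IL-1 receptor antagonist gene, at 5.41 ± 0.20 and ZFP36, which encodes an mRNA-destabilising protein, at 1.93. In the survival and apoptosis list 21 of 38 genes rose and 10 fell (21 and 10 over the list alone), with the smallest p for the anti-apoptotic BCL2A1 (2.97 ± 0.11) and BIRC2 (1.63). The pro-apoptotic PMAIP1 rose as well (1.74).

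Receptor genes moved both ways. Of 44 chemotactic, adhesion and pattern receptor genes, 21 rose and 18 fell (21 and 18 over the list alone). PTAFR rose by 1.95 and TLR4 by 1.43, and the IL-8 receptor genes CXCR1 (-2.63) and CXCR2 (-2.49) fell, the latter from 1785 to 339 CPM. Granule and NADPH oxidase genes counted 14 higher and 6 lower of 36 (14 and 6 over the list alone), including SLPI at 2.35 and the calprotectin gene S100A8 at 1.14. Among 49 interferon-stimulated genes 22 rose and 4 fell (22 and 4 over the list alone), with IDO1 at 2.10 and GBP1 at 1.74. In the cholesterol list 13 of 27 genes rose and 8 fell (13 and 8 over the list alone), with INSIG1, a sterol-sensing brake on cholesterol synthesis, at 2.90 ± 0.11 and HMGCS1 at 0.80. The stress response list had 20 of 32 genes higher and 8 lower (20 and 8 over the list alone), with DNAJB9 at 1.42 and TXN at 1.22, and the TLR4, TPL2 and MAPK pathway list 28 of 50 higher and 15 lower (29 and 15 over the list alone). The prostaglandin and leukotriene list had 13 of 21 genes higher and 6 lower (13 and 6 over the list alone), with PTGS2, the gene of COX-2, at 2.22 ± 0.20, FPR2 at 1.79 and LTA4H at -1.14. The cAMP-CREB and NR4A list had 10 of 19 higher and 6 lower (10 and 6 over the list alone), with PDE4B at 1.34 and CREB5 at -2.41. The glycolysis and hypoxia list had 12 of 40 higher and 18 lower (13 and 18 over the list alone), with PFKFB3 at 2.10 and HIF1A at 1.30. Its median was -0.23 and its mean 0.01, and camera gave the direction of the mean and fry that of the median.

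In all, 3777 genes rose and 4590 fell with LPS, 1265 and 1077 of them at least 2-fold, and without the donor block the calls of S100A8 and IDO1 were lost (adjusted p = 0.0724 and 0.12). With an estimated correlation, 5 lists kept their camera call for LPS: cytokines (adjusted p = 0.000108), NF-kB genes (0.007), ERK genes (0.00335), negative regulators (0.0323) and survival genes (0.0484). For the interferon-stimulated, granule, MAPK pathway, stress and cholesterol lists the adjusted p with an estimated correlation was 0.69, 0.419, 0.128, 0.197 and 0.34. Without the donor block 1940 genes rose and 2533 fell. The balance of rises and falls turned with upper-quartile scaling (4740 and 3879), DESeq2 size factors (4300 and 4174), DESeq2's own test (4178 and 4115) and without donor 1 (3915 and 3864). With library size alone, which shifted the median of all genes to -0.37, 18.3% of the calls were rises against 45.1%, and the medians of the receptor, granule, survival, MAPK pathway, stress, cholesterol and cAMP-CREB lists turned negative.

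The TPL2 inhibitor lowered a large set of the cytokine genes that LPS had raised. TNF fell by 1.97 ± 0.12 on the log2 scale, from 299 ± 117 to 79.3 ± 38.9 CPM (adjusted p = 3.43e-08), and IL6 fell by 1.92 ± 0.15 (adjusted p = 1.15e-06). IL1A fell by 2.34 and IL1B by 1.56 ± 0.15, from 4691 ± 1352 to 1622 ± 604 CPM (adjusted p = 9.14e-06). CXCL8 fell by 1.13 ± 0.12 (adjusted p = 9.14e-06) and remained above the unstimulated level at 7998 ± 2069 CPM. The largest falls among the more abundant genes were those of SERPINB2 (-3.74 ± 0.35), which encodes the inhibitor of urokinase PAI-2, the ERK-induced transcription factor gene ETV5 (-3.12 ± 0.40), DUSP6 (-2.44 ± 0.25), IL1A and the immediate early gene EGR3 (-2.07 ± 0.21). The largest rises among these genes were smaller: ALDH2, a mitochondrial aldehyde dehydrogenase gene, at 1.69 ± 0.25, TAMALIN at 1.57, the small nucleolar RNA host gene SNHG16 at 1.26, SIK1, a salt-inducible kinase gene, at 1.26 and ST6GALNAC2 at 1.14. MAP3K8 itself was at -0.15 ± 0.12 (adjusted p = 0.509), CCL3 at -1.10 ± 0.33 (adjusted p = 0.0525, lower in all 5 donors) and PTGS2 at -0.59 ± 0.19 (adjusted p = 0.0716).

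By list, 24 of 38 cytokine and chemokine genes fell with the TPL2 inhibitor and 2 rose (28 and 3 when adjusted over the list alone; camera adjusted p = 2.86e-38, and 0.000108 with an estimated correlation). Their summed level was 13399 ± 2412 CPM against 29775 ± 4606 CPM with LPS and vehicle, and IL36G fell by 2.64 ± 0.15 while IL12B and IL15 rose. Along with these, the means of the monocyte and eosinophil marker lists were -0.15 ± 0.05 and -0.14 ± 0.11 (SD), below 0 in 5 of 5 donors (fry adjusted p = 0.568 and 0.242). Their summed levels were 120 ± 51.9 against 136 ± 60.9 CPM with LPS and vehicle, and 165 ± 77.4 against 161 ± 70.5 CPM. Of 35 ERK target genes 15 fell and 2 rose (19 and 4 over the list alone; adjusted p = 0.000652 with an estimated correlation), among them SPRED2, a feedback inhibitor of the pathway, by 1.14 ± 0.09. Of 32 stress response genes 11 fell (12 lower and 2 higher over the list alone; adjusted p = 0.0298 with an estimated correlation). These included genes of glutathione and thioredoxin metabolism, GCLM at -1.03 ± 0.09, SLC7A11 at -1.23 and TXNRD1 at -0.53, and the chaperone gene HSPA5. Of 41 NF-kB genes 5 fell (7 over the list alone; adjusted p = 0.656 with an estimated correlation), namely STEAP4 (-1.38), G0S2, SOD2, IER3 (-0.42) and NAMPT, while 36 did not pass the test. The median of the list was -0.08, and 0.04 with library size alone. Without the unstimulated libraries 15 of the 41 were called lower and 1 higher, against 25 and 4 of 37 cytokine, 20 and 4 of 35 ERK target and 12 and 2 of 32 stress response genes.

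Of 44 receptor genes 12 fell and 2 rose (15 and 4 over the list alone; adjusted p = 0.151 with an estimated correlation). They included genes of the microbial sensing machinery: TLR2 (-1.31), CD14 (-1.20), TREM1 (-0.62) and TLR4 (-0.38). Negative regulators had 11 of 35 lower and 1 higher (14 and 3 over the list alone; adjusted p = 0.0953 with an estimated correlation), with the decoy receptor gene IL1R2 at -1.54 ± 0.16, ZFP36 at -0.63 and IL10 at -0.95. Of 36 granule and oxidase genes 7 fell and 1 rose (11 and 2 over the list alone; adjusted p = 0.245 with an estimated correlation), including SLPI (-0.95) and the oxidase subunit gene NCF1 (-0.82), whose counts are uncertain because its pseudogenes are near-identical. The median of the granule list was -0.09, and 0.02 with library size alone. The cholesterol list went the other way, with 7 of 27 genes higher and 1 lower (8 and 1 over the list alone; adjusted p = 0.127 with an estimated correlation). Those that rose included genes of enzymes of the later steps of synthesis, MSMO1 (0.55 ± 0.09), CYP51A1 (0.46) and SC5D (0.44 ± 0.07), while INSIG1 fell by 0.52. The survival list had 4 of 38 higher and 5 lower (6 and 8 over the list alone), with the pro-apoptotic BBC3 at 0.57 and the inflammatory caspase gene CASP4 at -0.50, and the MAPK pathway list 5 higher and 5 lower of 50 (6 and 8 over the list alone), with MAPKAPK2 at -0.35, a median of 0.01 and a mean of -0.04. In the cAMP-CREB list 3 of 19 rose and 1 fell (4 and 2 over the list alone), with PER1 at 0.62, in the prostaglandin list 2 of 21 rose and 2 fell (2 and 3 over the list alone), with FPR2 at -0.72 and ALOX5AP at -0.52, and in the glycolysis list 1 of 40 rose and 3 fell (2 and 4 over the list alone), with BNIP3L at 0.42 and PFKFB3 at -0.87. No interferon-stimulated gene of the 49 was called by edgeR, limma-voom or DESeq2, 1 having an unadjusted p under 0.05 in each of them, and the fit without the unstimulated libraries called 2 of 48 higher. IDO1 was at 0.31 (adjusted p = 0.162). The median of this list was -0.04, although camera placed it upward. With library size alone the medians of the interferon-stimulated, survival, prostaglandin and glycolysis lists turned positive, at 0.08, 0.06, 0.05 and 0.09. Without the unstimulated libraries the calls were 22 lower and 5 higher for receptors, 16 and 3 for negative regulators, 12 and 5 for granule genes, 4 and 14 for cholesterol, 9 and 8 for survival, 12 and 11 for MAPK pathway, 4 and 5 for cAMP-CREB, 6 and 4 for prostaglandin and 8 and 6 for glycolysis genes.

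In all, 604 genes rose and 827 fell with the TPL2 inhibitor, 29 and 84 of them at least 2-fold, out of 3311 with an unadjusted p under 0.05. Of the 827 genes that fell, LPS had raised 651 and lowered 72, and of the 604 that rose, LPS had lowered 350 and raised 150. Both comparisons use the same LPS libraries, but the 2 sets of changes also correlated negatively across genes when they were taken from different donors (median r = -0.33 over 20 splits, from -0.47 to -0.13; genes are not independent replicates). Without the donor block 1 gene rose and 10 fell, and without the unstimulated libraries, a fit added after seeing the data, 1522 rose and 1671 fell, among them 1423 of the 1431 genes called here. With library size alone 79.3% of the calls were rises, against 42.2%, at a median of all genes of 0.10. Without donors 1, 2, 4 or 5 the counts came to 711 and 652, 340 and 533, 270 and 393, and 318 and 433, and without at least 1 of them SIK1, PER1 and BNIP3L lost their call.

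**Figure D2:**
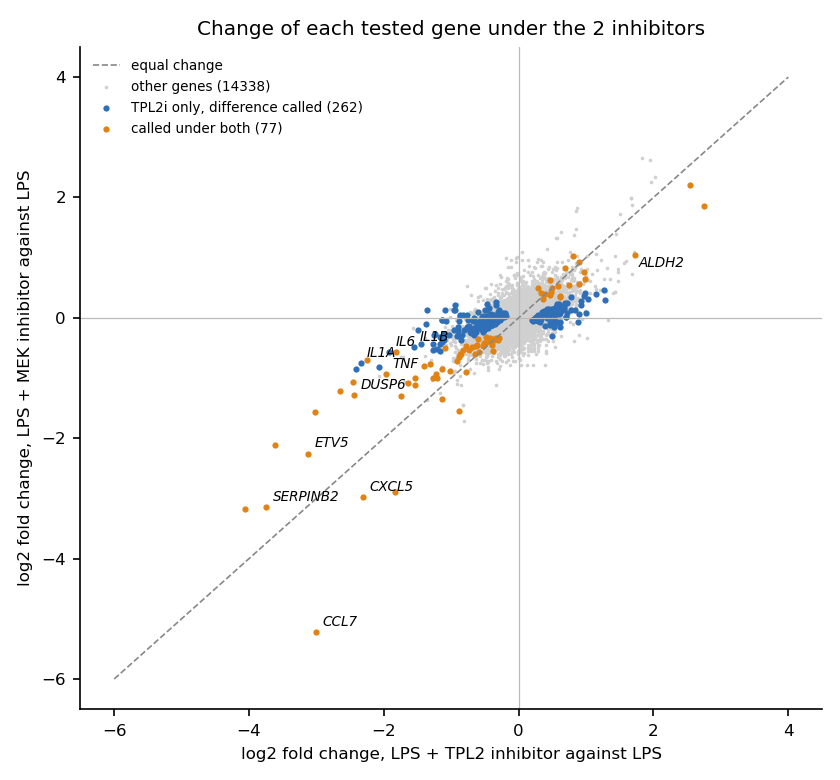
Log2 fold change of each tested gene under the MEK inhibitor (vertical axis) against that under the TPL2 inhibitor (horizontal axis), both relative to LPS with vehicle; the dashed line marks equal change. Orange points are the 77 genes called in the same direction under both inhibitors, blue points the 98 higher and 164 lower genes called under the TPL2 inhibitor and in the direct difference but not under the MEK inhibitor, and most coloured points on the left lie above the line.

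The MEK inhibitor lowered some of the ERK target genes, and fewer of the cytokine genes than the TPL2 inhibitor did. SERPINB2 fell by 3.14 ± 0.33, from 186 ± 188 to 18.4 ± 13.8 CPM (adjusted p = 0.000292), and ETV5 by 2.26 ± 0.38 (adjusted p = 0.0148). DUSP6 fell by 1.28 ± 0.24, from 492 ± 135 to 210 ± 91.2 CPM (adjusted p = 0.0311). TNF fell by 0.93 ± 0.12 to 161 ± 70.0 CPM (adjusted p = 0.000399). The chemokine genes CCL7, CXCL5 and CXCL3 fell by 5.22 ± 0.54, 2.98 ± 0.27 and 1.09 ± 0.15. CCL7 was already low with LPS and vehicle, at 2.71 ± 3.52 CPM (donors from 0.187 to 8.80), and went to 0.0792 ± 0.0966 CPM. Among genes with a mean log2 CPM of at least 3 the largest falls also included CKAP2L at -1.06. The largest rises among these more abundant genes were below 1 log2 unit: TBC1D9 at 0.76, the IL-6 family cytokine gene CLCF1 at 0.64, MS4A7, a member of the monocyte marker list, at 0.63, the pseudogene FAM86B3P at 0.55, which shares sequence with its gene family, and NHSL2 at 0.53. IL6 (-0.57 ± 0.14, adjusted p = 0.121), IL1B (-0.48 ± 0.15, adjusted p = 0.245) and CXCL8 (-0.40 ± 0.12, adjusted p = 0.203) did not pass the test, although each was lower in all 5 donors. CCL3 (-0.23), PTGS2 (0.06) and MAP3K8 (0.06) had adjusted p-values of 0.967, 0.998 and 0.983.

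Of 38 cytokine and chemokine genes 7 fell (15 lower and 3 higher when adjusted over the list alone; camera adjusted p = 8.47e-18, and 0.000652 with an estimated correlation): CCL7, CXCL5, CCL2, IL36G, CXCL3, TNF and CXCL1. The monocyte and eosinophil marker lists had means of -0.07 ± 0.10 and -0.08 ± 0.04 (SD), below 0 in 4 and 5 of 5 donors (fry adjusted p = 0.885 and 0.782). Of 35 ERK target genes 6 fell (16 lower and 1 higher over the list alone; adjusted p = 0.000235 with an estimated correlation): SERPINB2, ETV5, DUSP6, EGR1 (-0.89 ± 0.10), SPRED2 (-0.86 ± 0.09) and MAFF. The negative regulator IL1R2 fell by 0.99 ± 0.16, the only call of edgeR and limma-voom among 35 (1 higher and 2 lower over the list alone). DESeq2 called 1 higher and 1 lower in this list, and edgeR's fit without the unstimulated libraries 1 higher and 4 lower. NCF1 (-0.54) and RAC2 (-0.36) fell among 36 granule and oxidase genes (2 over the list alone), ITGAM (-0.35) among 44 receptor genes (2 over the list alone) and PIM1 (-0.33) among 38 survival genes (1 over the list alone). Without the unstimulated libraries the calls were 9 lower and 2 higher for cytokine, 16 lower for ERK target, 6 lower for granule, 7 lower and 1 higher for receptor and 2 lower and 1 higher for survival genes.

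Interferon-stimulated genes lay higher with the MEK inhibitor as a group, without any single call in edgeR. All 49 tested members were above 0, with a median of 0.52 and a camera adjusted p of 1.34e-25, but with an adjusted p = 0.127 with an estimated correlation, since these genes vary together. The list mean was above 0 in 5 of 5 donors, 0.50 ± 0.28 (SD), and IDO1 was at 0.57 (adjusted p = 0.0589) and IFI44L at 0.85 (adjusted p = 0.212). Of the 49 genes, 32 had an unadjusted p under 0.05, 1 was called when adjusted over the list alone, DESeq2 called 3 and limma-voom 0 (17 unadjusted), and the fit without the unstimulated libraries called 27 of 48.

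**Figure D3:**
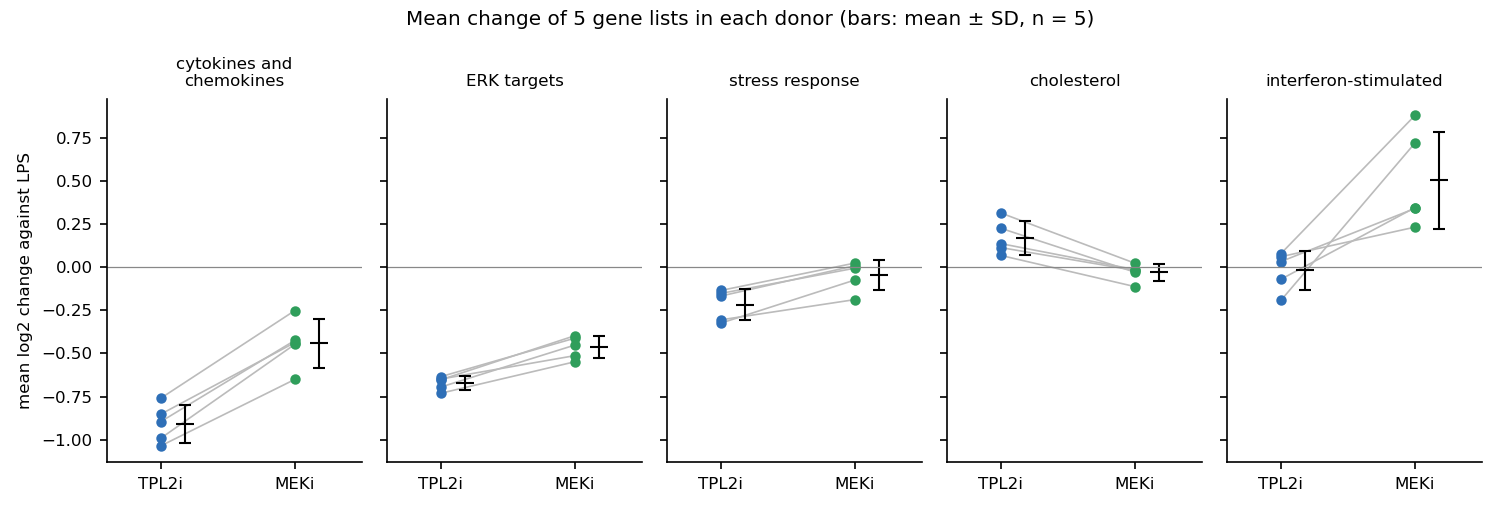
Mean log2 fold change over the tested genes of 5 lists in each of the 5 donors (points), with the mean ± SD over donors (bars), under the TPL2 inhibitor and the MEK inhibitor relative to LPS with vehicle. Under the MEK inhibitor the interferon-stimulated list has a mean of 0.50, with all donors between 0.23 and 0.88, and under the TPL2 inhibitor a mean of -0.02, with donors on both sides of 0.

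In the NF-kB (41 genes), cAMP-CREB (19), prostaglandin (21), glycolysis (40), MAPK pathway (50), stress (32) and cholesterol (27) lists no gene was called by edgeR with the MEK inhibitor in the fit of 20 libraries. Without the unstimulated libraries the calls were 1 higher and 2 lower, 2 higher, 2 and 2, 2 and 1, 1 and 3, 1 and 3, and 1 lower. At an unadjusted p under 0.05 the fit of 20 libraries had 4, 7, 4, 3, 6, 7 and 1. DESeq2 called 1 gene lower in each of the NF-kB, MAPK pathway and stress lists and 0 in the other lists, and limma-voom called 0. Adjusted over the list alone, the counts were 1 higher and 1 lower, 5 higher, 2 higher, 0, 1 higher and 2 lower, 1 higher and 3 lower, and 0. The median of the NF-kB list lay within rounding of 0, where camera, its mean and the scalings differed in sign, and the MAPK pathway list had a median of 0.03 and a mean just below 0. The camera adjusted p of the cAMP-CREB list was 0.00229, with CREM at 0.27 and PDE4A at 0.26, and it was 0.0508 with an estimated correlation. In the other lists the members with the smallest p included CD80 (0.57), PLA2G4A (0.64), BNIP3L (0.34), MKNK1 (-0.28) and TRIB3 (-0.54), none of which passed the test.

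In all, 25 genes rose and 61 fell with the MEK inhibitor, 6 and 21 of them at least 2-fold, out of 1203 with an unadjusted p under 0.05. Without the donor block edgeR called 0 genes (113 with an unadjusted p under 0.05). With the block DESeq2 called 46 higher and 88 lower and limma-voom 19 and 56, and edgeR's fit without the unstimulated libraries called 237 and 305, including 85 of the 86 genes. Of the 20 called named genes 12 lost their call without at least 1 donor, DUSP6 and ETV5 among them, and that of DUSP6 was also lost without the filter on low counts (adjusted p = 0.0513). The calls of ITGAM, PIM1 and RAC2 ended whichever donor was left out. Without donors 2, 3, 4 or 5 the counts were 5 and 21, 13 and 32, 7 and 17, and 5 and 19.

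The direct comparison of the 2 inhibitors tested which genes respond to them differently. Cytokine genes were lower with the TPL2 inhibitor than with the MEK inhibitor: IL1A by 1.59 ± 0.21 on the log2 scale, with 162 ± 55.0 against 488 ± 109 CPM (adjusted p = 0.0017). IL6 was at -1.35 ± 0.15 (adjusted p = 0.000273), IL1B at -1.08 ± 0.15 (adjusted p = 0.00154), TNF at -1.04 ± 0.12 (adjusted p = 0.000273) and CXCL8 at -0.73 ± 0.12 (adjusted p = 0.00265). DUSP6 was lower too, at -1.16 ± 0.25 (adjusted p = 0.026), as were EGR3 (-1.25) and ARRDC4 (-1.29), an arrestin-domain gene induced by MondoA, a transcription factor that responds to glucose. SCD, a fatty acid desaturase gene (0.67 ± 0.13), SNHG16 (0.80), ST6GALNAC2 (0.75) and the corepressor gene CBFA2T3 (0.70) were higher with the TPL2 inhibitor. CCL3 (-0.87, adjusted p = 0.227), PTGS2 (-0.65, adjusted p = 0.11) and MAP3K8 (-0.21, adjusted p = 0.45) did not pass the test. The doses of the inhibitors and how fully each blocked its kinase are not given in the sources used here, so the sizes of the responses are those of 2 treatments of unmatched strength.

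In this comparison 12 of 38 cytokine genes were lower and 0 higher (24 and 2 when adjusted over the list alone; adjusted p = 0.000235 with an estimated correlation), and 5 of 32 stress response genes were lower (12 lower and 1 higher over the list alone; adjusted p = 0.0292 with an estimated correlation), including GCLM (-0.73 ± 0.09) and the cystine transporter gene SLC7A11 (-0.97 ± 0.17). Of 27 cholesterol genes 7 were higher and 1 lower (10 and 1 over the list alone; adjusted p = 0.0471 with an estimated correlation), with the smallest p for MSMO1 (0.62 ± 0.09) and SC5D (0.42 ± 0.07). Of 35 ERK target genes 3 were lower and 1 higher (8 and 1 over the list alone; adjusted p = 0.0953 with an estimated correlation). Smaller numbers were lower among the receptor genes (3 of 44, with 1 higher), which included TREM1 and TLR4, the negative regulators (3 of 35), which included DUSP1 (-0.47) and ZFP36 (-0.47), and the granule genes (2 of 36), S100A8 and S100A12. Over the list alone these were 7 lower and 1 higher, 8 lower and 4 lower, with an adjusted p of 0.13, 0.127 and 0.245 with an estimated correlation. Among survival genes PMAIP1 (-0.96), which encodes the pro-apoptotic NOXA, and CASP4 (-0.32) were lower and 1 of 38 was higher (3 and 2 over the list alone). NAMPT was the 1 call of edgeR among 41 NF-kB genes, TLR4 among 50 MAPK pathway genes and THBS1 (-0.70) among 19 cAMP-CREB genes (1 each over the list alone), where DESeq2 called 4, 2 and 1 lower. Without the unstimulated libraries the calls were 13 lower for NF-kB, 6 lower and 4 higher for MAPK pathway, 3 and 1 for cAMP-CREB, 5 and 1 for prostaglandin and 7 and 1 for glycolysis genes. They were 19 and 1 for cytokine, 10 and 1 for stress response, 3 and 11 for cholesterol, 12 and 2 for ERK target, 17 and 2 for receptor, 12 and 1 for negative regulator, 8 and 1 for granule and 5 and 5 for survival genes. FPR2 and ALOX5AP were lower among 21 prostaglandin genes (4 over the list alone). The NF-kB and prostaglandin lists had an adjusted p of 0.553 and 0.0953 with an estimated correlation, against 0.00146 and 0.0412 from camera. Of 40 glycolysis genes edgeR and limma-voom called 0 and DESeq2 1, with 4 at an unadjusted p under 0.05 in edgeR and 0 over the list alone, PFKFB3 being at -0.48 (adjusted p = 0.1). With library size alone the medians of the survival, glycolysis, MAPK pathway and cAMP-CREB lists turned positive, each to below 0.10. IFI44L, at 17.9 ± 25.0 against 35.2 ± 50.3 CPM and lower in all 5 donors (adjusted p = 0.0493), was the 1 interferon-stimulated gene of 49 called by edgeR (5 over the list alone; DESeq2 7, limma-voom 0). The median of that list was -0.57 (camera adjusted p = 9.07e-16, and adjusted p = 0.232 with an estimated correlation), and the fit without the unstimulated libraries called 32 of 48 lower.

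In all, 110 genes were higher and 192 lower with the TPL2 inhibitor than with the MEK inhibitor, 0 and 24 of them at least 2-fold, out of 2093 with an unadjusted p under 0.05. Without the donor block edgeR called 0 (233 with an unadjusted p under 0.05). With the block DESeq2 called 191 and 321 and limma-voom 98 and 178. The fit without the unstimulated libraries called 742 and 948, including all 302, and library size alone called 435 and 112, so that 79.5% against 36.4% were higher. Without donors 2, 4 or 5 the counts were 35 and 84, 19 and 45, and 17 and 37. Of the 31 called named genes 21 lost their call without at least 1 donor, DUSP6 and EGR3 among them, and IFI44L and S100A8 whichever donor was left out.

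**Figure D4:**
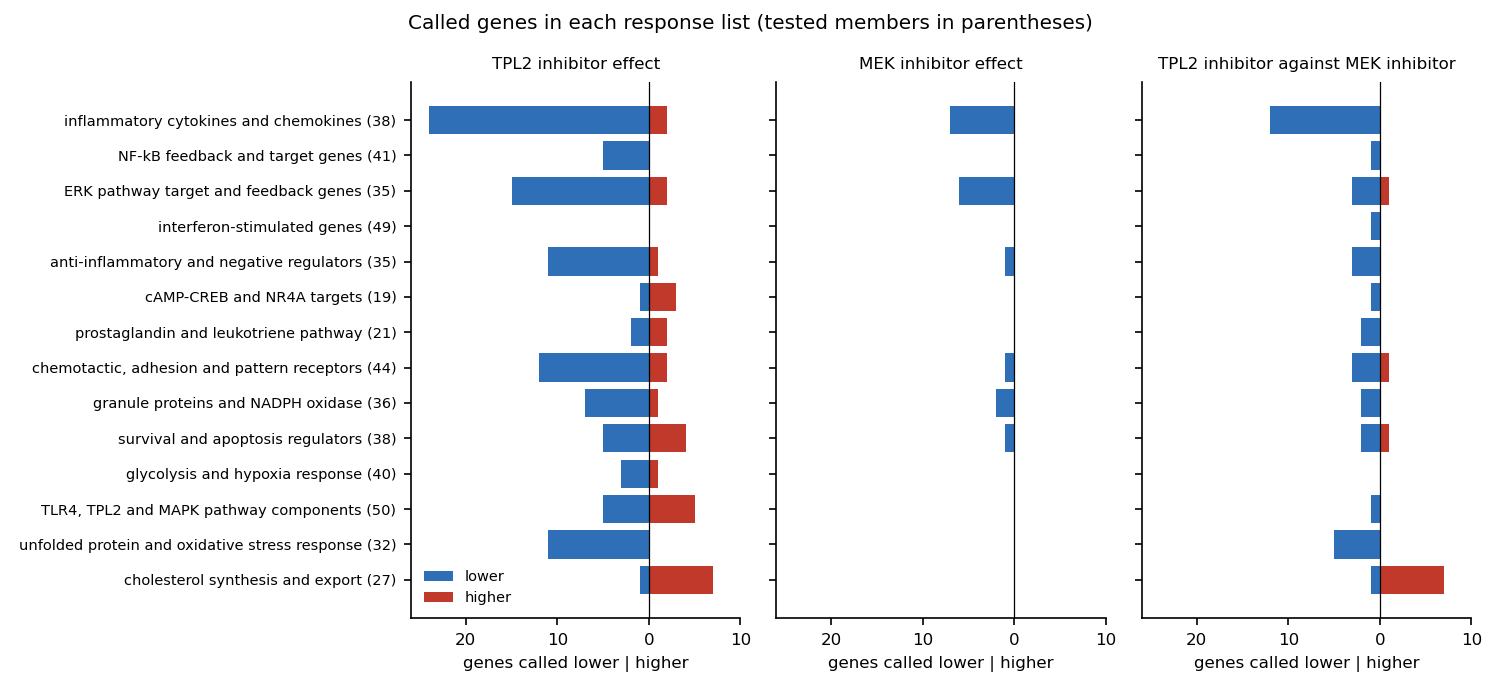
Number of genes called lower (blue, to the left) and higher (red, to the right) in each of 14 gene lists, for the TPL2 inhibitor, the MEK inhibitor and the direct difference between them; the number of tested genes stands in parentheses. The cytokine list has 24, 7 and 12 genes called lower, and the cholesterol list 7, 0 and 7 called higher.

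The genes called under the MEK inhibitor were nearly all called under the TPL2 inhibitor as well. Of the 61 genes that fell with the MEK inhibitor 56 fell with the TPL2 inhibitor, and of the 25 that rose 21 did, where independent lists would share 3.44 and 1.03. No gene was called in opposite directions, and all 86 had the same sign under the TPL2 inhibitor. Genes lowered by both included SERPINB2, ETV5, DUSP6, SPRED2, EGR1, TNF, IL36G, CXCL3 and IL1R2. Both comparisons share the LPS libraries, so their changes correlate by chance. Across genes r was 0.65 (genes are not independent replicates), against 0.49 ± 0.02 (SD, 20 draws) in simulated unchanged groups, and the covariance was 0.0403 against 0.0138, a difference of 0.0265. With the 2 comparisons taken from different donors the covariance was 0.0249 (median of 20 splits, from 0.0178 to 0.0278). In these splits a median of 6 genes fell in both (from 0 to 26) and a median of 0 rose in both (from 0 to 3), where independent lists would share 0.118 and 0.0222. DESeq2 found 37 genes higher and 81 lower in both, the fit without the unstimulated libraries 163 and 273, and that without the donor block 0. Without donors 2, 3, 4 or 5 the counts were 5 and 20, 9 and 32, 7 and 16, and 5 and 17.

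A class of genes that responded to the TPL2 inhibitor and differed between the inhibitors, without a call for the MEK inhibitor, held 98 genes that were higher and 164 that were lower. Of the 164 lower genes LPS had raised 143 and lowered 4, and their median changes were -0.50 with the TPL2 inhibitor and -0.06 with the MEK inhibitor. This part included IL1A, IL1B, IL6, CXCL8, EGR3, ARRDC4, GCLM, SLC7A11, ZFP36, DUSP1, TREM1 and TLR4. Of the 98 higher genes LPS had lowered 53 and raised 24, their medians were 0.52 and 0.07, and they included SNHG16, MSMO1 and SC5D. Membership says that the responses differed, not that the MEK inhibitor had no effect, since 119 of the 164 and 74 of the 98 had the same sign under it. In simulated data with unchanged groups, or with equal effects of both inhibitors, at most 1 gene per direction entered the class. The equal effects gave a mean of 2011 calls for the MEK inhibitor, against 86 in the data. A MEK inhibitor that acts more weakly on the same genes was not simulated, so the simulations cannot tell such weaker action from a separate response. DESeq2 placed 159 and 254 genes in it, the fit without the unstimulated libraries 558 and 656, library size alone 389 and 94 and the fit without the donor block 0, and without donors 2, 4 or 5 it held 30 and 70, 17 and 37, and 16 and 30.

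For the middle gene, most of the log2 change with LPS remained under either inhibitor. This median does not describe every gene: the summed level of the cytokine genes fell well below that with LPS and vehicle under the TPL2 inhibitor, as given above. Among genes that changed at least 2-fold with LPS in some donors, the median share of that change kept in the other donors was 89.6% with the TPL2 inhibitor and 97.0% with the MEK inhibitor (medians of 20 splits, from 81.4% to 96.1% and from 91.9% to 101%; 1971 to 2844 genes). By donor the shares were 88.5% ± 8.89 and 96.3% ± 5.00 (SD, n = 5). For genes raised by LPS the difference was 8.06 ± 4.38 percentage points, in the same direction in 5 of 5 donors, with p = 0.0625 in a two-sided exact permutation test, the smallest this design allows. Over all genes it was 7.87 ± 5.06 points, in 4 of 5 donors (exact permutation p = 0.125).

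The purity of the neutrophils was stated as at least 99%. No marker list of another blood cell passed camera in any comparison with an estimated correlation (adjusted p = 0.995 in each). The cells of each donor were divided over the 4 groups, so other cells would be present in all of them. Comparisons between groups therefore do not measure purity. Without LPS the summed monocyte markers were at 360 CPM in donor 3 and at 111 to 153 CPM in the other donors. By fry the monocyte list was lower with LPS (adjusted p = 0.00208), with a mean of -0.56 ± 0.30 (SD) that lay below 0 in 5 of 5 donors while the cytokine genes rose, as was the neutrophil list (adjusted p = 1.51e-05). The most abundant monocyte marker, CSF1R, stood at 59.3 ± 29.3 CPM without LPS and 19.9 ± 13.4 with LPS. The eosinophil marker CCR3 stood at 215 ± 63.7 and 52.5 ± 31.1, the T cell marker IL7R at 71.4 ± 17.1 and 84.8 ± 18.1, the B cell marker CD22 at 28.8 ± 34.0 and 46.1 ± 36.1, the platelet marker TUBB1 at 4.13 ± 1.59 and 3.87 ± 1.13, and the red cell marker HBB at 21.2 ± 9.62 and 22.6 ± 12.4 CPM. With LPS 8 of 12 neutrophil markers fell and 3 rose (8 and 4 over the list alone), and their summed level was 5238 ± 1824 CPM against 10921 ± 3523. Of 11 monocyte markers 8 fell and 3 rose (8 and 3 over the list alone), of 14 eosinophil markers 4 fell and 4 rose (5 and 4 over the list alone), and 5 of 17 T and NK, 3 of 10 B cell and 1 of 9 platelet markers rose, with 2 platelet markers lower (3, 1, and 1 higher and 1 lower over the list alone). The eosinophil list had a median of -0.13 and a mean of 0.20. With the TPL2 inhibitor the calls were 1 higher and 2 lower in each of the monocyte, eosinophil and neutrophil lists, and with the MEK inhibitor 1 higher (MS4A7) and 1 lower among the monocyte markers. Between the inhibitors 1 eosinophil marker was lower. The counts over the list alone were the same, apart from 2 higher and 2 lower neutrophil markers, 1 lower monocyte and 1 lower B cell marker between the inhibitors, where edgeR called 0 over all genes (5, 3 and 2 with an unadjusted p under 0.05) and DESeq2 called 2, 1 and 0 and limma-voom 0. The 3 tested red cell markers had no call by edgeR, DESeq2 or limma-voom in any comparison, and an unadjusted p under 0.05 in 0 of them. Of 13 mitochondrially encoded genes 7 rose with LPS (9 over the list alone), to a summed 4613 ± 1253 from 3826 ± 754 CPM, and in the MEK inhibitor comparison their median was -0.14 (camera adjusted p = 0.00999, 0.995 with an estimated correlation). With library size alone the medians of the T and NK, B cell and mitochondrial lists turned negative for LPS. Of 40 ribosomal protein genes 1 rose and 1 fell with LPS (0 over the list alone), and their summed level was 5036 ± 961 against 5049 ± 956 CPM.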

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

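The search for a donor far from the others was planned, and no test in this part was chosen after the result was seen. In each group of 5 donor values, the gap of the highest or lowest value to the nearest of the others was divided by the whole range and set against a critical value of 0.71. Of 269 groups of values 22 passed it (8.18%), where chance passes about 1 in 20, among them 15 of 167 values of named genes, 3 of 56 of response lists, 2 of 36 of marker lists and 2 of 4 of TMM factors. None of 4 sets of library sizes and none of 2 sets of shares of the LPS response kept did (0 of each). The donor furthest out was donor 1 in 9 of the 22, donor 2 in 4, donor 3 in 6, donor 4 in 1 and donor 5 in 2, and no explanation was tested. Below, each ratio stands in parentheses and values are log2 changes within a donor.

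For LPS, the ribonuclease gene RNASE6 was at -4.41 in 1 donor against -3.57 to -3.28 in the others (0.741). PTAFR, the gene of the platelet-activating factor receptor, was at 2.25 against 1.84 to 1.95 (0.715), and NFKB1 at 3.39 against 2.71 to 2.90 (0.716). With the TPL2 inhibitor, the sialyltransferase gene ST6GALNAC2 was at 0.69 against 1.17 to 1.34 (0.737). TLR2 stood at -1.04 against -1.40 to -1.31 (0.753), and ALOX5AP, whose product serves leukotriene synthesis, at -0.29 against -0.61 to -0.54 (0.774). With the MEK inhibitor, the decoy receptor gene IL1R2 was at -0.83, against a lowest value of -1.06 (0.747), and NCF1 at -0.13 against -0.67 to -0.54 (0.765). The phospholipase gene PLA2G4A stood at 0.22 against 0.63 to 0.78 (0.724), and CCL3 at 0.19 in 1 donor against -0.38 to -0.31 in the others (0.872), so that its direction differed between donors.

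Between the inhibitors, SNHG16 was at 0.36 in 1 donor against 0.89 to 0.94 in the others (0.904) and ST6GALNAC2 at 0.28 against 0.79 to 0.98 in the same comparison (0.731). PMAIP1, the gene of NOXA, was at -1.67 against -0.86 to -0.66 (0.804), and the kinase gene MAPKAPK2 at -0.27 against -0.15 to -0.11 (0.716). CCL3 was at -1.11 against -0.87 to -0.78 (0.738). Among list means, that of glycolysis and hypoxia genes was -0.15 against -0.02 to 0.03 with the TPL2 inhibitor (0.715) and 0.31 against -0.06 to 0.04 with the MEK inhibitor (0.732). The negative regulators had a mean of -0.14 against -0.08 to -0.06 with the MEK inhibitor (0.863). Between the inhibitors the monocyte markers had -0.30 against -0.06 to 0.03 (0.720) and the neutrophil markers -0.26 against 0.01 to 0.11 (0.726), both in donor 1. The TMM factor of donor 1 was 0.713 against 0.943 to 1.03 with the MEK inhibitor (0.732) and 0.961 against up to 1.28 in unstimulated cells (0.748).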

How the results depend on the processing

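The fit of the 15 libraries of the 3 LPS groups was chosen after the fit of 2 groups alone had been seen, and the other alternatives were planned. No named gene with a call in either of the settings compared reversed its direction. No list test with such a call did so with an estimated correlation, with fry or without the donor block. List tests were not run with other scalings, and with library size alone the medians of several lists turned, as given above. The glycolysis list, without a call for LPS, was up by camera (adjusted p = 0.974) and down by fry (0.982). The balance of rises and falls turned for LPS with the upper quartile (4740 and 3879), DESeq2 size factors (4300 and 4174), DESeq2's Wald test (4178 and 4115), without donor 1 (3915 and 3864) and at a 2-fold minimum. It turned for the TPL2 inhibitor without donor 1 (711 and 652), and with library size alone for the TPL2 inhibitor, the direct comparison and the class of genes. Other scalings by DESeq2 size factors or the upper quartile, both filters and limma-voom kept every count of called genes within 1.5 times. With library size alone in place of TMM, 1932 genes rose and 8651 fell with LPS, 1621 and 423 with the TPL2 inhibitor, 435 were higher and 112 lower in the direct comparison and the class of genes held 389 and 94, and the median of all genes moved to -0.37 for LPS, 0.10 for the TPL2 inhibitor and 0.09 for the direct comparison. DESeq2's Wald test gave 46 rises with the MEK inhibitor, 191 and 321 in the direct comparison, 159 and 254 in the class and 37 genes higher under both inhibitors. Without the donor block 1940 rose and 2533 fell with LPS, 1 and 10 with the TPL2 inhibitor (603 at an unadjusted p under 0.05), 0 and 0 with the MEK inhibitor (113) and 0 and 0 in the direct comparison (233), so that class and overlap held 0. With the block, DESeq2 and limma-voom called 134 and 75 genes for the MEK inhibitor and 512 and 276 in the direct comparison. Without it donor differences enter the error, as the block's construction shows. With the 10 libraries of the 2 groups compared, the TPL2 inhibitor had 1112 rises, the MEK inhibitor 520 and 570 calls and the direct comparison 754 and 934. The 3 LPS groups gave 1522 and 1671, 237 and 305, and 742 and 948, with 558 and 656 in the class and 163 and 273 in the overlap, among 14377 tested genes and with 8 residual degrees of freedom. A 2-fold minimum left 1265 and 1077 genes for LPS, 29 and 84 for the TPL2 inhibitor, 6 and 21 for the MEK inhibitor and 0 and 24 in the direct comparison. Leaving out each donor in turn, which also lowers the number of libraries, gave 3511 to 3915 rises and 3864 to 4440 falls with LPS, 270 to 711 and 393 to 736 with the TPL2 inhibitor, 5 to 24 and 17 to 53 with the MEK inhibitor, 17 to 145 and 37 to 214 in the direct comparison, 16 to 131 and 30 to 178 in the class and 5 to 22 and 16 to 50 in the overlap. For the inhibitors the lowest values came without donor 4 or 5, and for rises with the MEK inhibitor and in the overlap also without donor 2. The share of the LPS response kept ranged from 85.8% to 91.1% with the TPL2 inhibitor and from 95.7% to 98.5% with the MEK inhibitor. Of the list tests 32 passed with camera, 13 with an estimated correlation, 32 with fry (4 lost and 4 gained) and 27 without the donor block. Among the named genes, scaling, filter and tool ended 0 of 40 calls for LPS, 0 of 37 for the TPL2 inhibitor, 7 of 20 for the MEK inhibitor (DUSP6, TBC1D9, CLCF1, FAM86B3P, ITGAM, RAC2 and PIM1) and 5 of 31 in the direct comparison (ST6GALNAC2, S100A8, IFI44L, NAMPT and FPR2). Leaving out a donor ended 0, 3, 12 and 21, those of ITGAM, PIM1 and RAC2 with the MEK inhibitor and IFI44L and S100A8 in the direct comparison whichever donor was left out. The fit without the donor block ended 2, 32, 20 and 31. The causes of these moves were not tested beyond what is stated. Depth was not varied. At the depths and donor number of these libraries the simulated recovery at 1.5-fold was 71.6%, 62.7% and 80.6%, so that a gene without a call is not shown to be unchanged. The simulation held no LPS response beyond the genes changed on purpose, and 1 dispersion per gene for all groups. It therefore does not give the recovery of each real comparison.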

Other observations

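Apart from the counts over other splits of the libraries, the tests in this part were chosen after the result was seen, and the genes named in the first paragraphs were picked after their values were seen, all from edgeR's test with Benjamini-Hochberg adjustment. TXNIP, which encodes a brake on glucose uptake and a target of MondoA, rose by 0.81 with LPS and fell by 1.08 ± 0.15 with the TPL2 inhibitor (adjusted p = 0.000269). It was at -0.05 with the MEK inhibitor (adjusted p = 0.999), and the difference between the inhibitors was -1.04 ± 0.15 (adjusted p = 0.00209), in 5 of 5 donors. ARRDC4, another MondoA target, fell by 1.49 and was at -0.20 with the MEK inhibitor (adjusted p = 0.838). OSGIN1, SRXN1 and TXNRD1, genes induced by the oxidant-responsive factor NRF2, fell with the TPL2 inhibitor (-1.16, -0.50 and -0.53) and were lower than with the MEK inhibitor (-0.72, -0.40 and -0.39, adjusted p = 0.004, 0.0129 and 0.0129). NQO1 fell by 0.79 and differed by -0.62 (adjusted p = 0.0566), whereas HMOX1 was at 0.14 (adjusted p = 0.748). Among cytokines, CSF2, the gene of GM-CSF, fell by 2.41 ± 0.23 with the TPL2 inhibitor and differed by -1.56 between the inhibitors (adjusted p = 0.00328), and IL23A stood at -0.83 and -0.87 (adjusted p = 0.0324 for the difference). ACOD1, the gene of the enzyme that makes itaconate, rose by 7.85 with LPS and was lower with the TPL2 than with the MEK inhibitor (-0.97, adjusted p = 0.00265).

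Some genes moved with both inhibitors. CFB, the gene of complement factor B, which LPS raised by 5.12, rose further, by 1.72 ± 0.16 with the TPL2 inhibitor and 1.05 ± 0.17 with the MEK inhibitor (adjusted p = 7.69e-06 and 0.00709). GJB2, a connexin gene, rose by 0.80 and 1.03, and KLF4, a transcription factor gene at 1.29 ± 0.81 CPM with LPS, by 0.69 and 0.84. TFPI2, which encodes a protease inhibitor, fell with both (-4.05 and -3.17), from a low 1.43 ± 2.23 CPM. The calcium-signalling gene IRAG1 fell by 1.28 with the TPL2 inhibitor and had the smallest p of the MEK inhibitor comparison (adjusted p = 5.54e-05). Tissue factor, the gene F3, rose by 6.51 with LPS, fell by 1.14 ± 0.20 with the TPL2 inhibitor (adjusted p = 0.00204) and was at -0.81 ± 0.19 with the MEK inhibitor (adjusted p = 0.107). FASN, the fatty acid synthase gene, was higher with the TPL2 than with the MEK inhibitor by 0.48 ± 0.09 (adjusted p = 0.00789), as was SQLE of cholesterol synthesis by 0.48 ± 0.11 (adjusted p = 0.0353).

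The calls were set against other splits of the same 10 libraries into 5 and 5, of which 100 of the 126 were drawn, the real one included. Only the real split, 1 of 100, reached the number of calls in each comparison. For LPS it called 8367 genes and the highest other split 5896, which parted 3 donor pairs and kept 2 together, so that the split itself follows part of the LPS difference. For the TPL2 inhibitor the numbers were 1431 and 3, for the MEK inhibitor 86 and 1, and for the direct comparison 302 and 8. Among the 12, 12, 13 and 12 drawn splits that part all donor pairs as the real one does, the highest others called 3411, 2, 1 and 6 genes. The other drawn splits keep donor pairs together, which puts the difference between the groups into their error. Only splits that part all pairs compare like with like, and 12 or 13 of them are too few to exclude chance in the split. The fit of the 3 LPS groups was not examined in this way.

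The effect of the MEK inhibitor was smaller than that of the TPL2 inhibitor. Lower depth is argued against by a ratio of mean total counts of 0.978. If the MEK inhibitor did the same as the TPL2 inhibitor at a fixed fraction, its change minus 47.4% of that of the TPL2 inhibitor would be near 0 for every gene: edgeR called 2 genes lower than this fraction predicts in the fit of 20 libraries (902 at an unadjusted p under 0.05) and 177 in that of the 3 LPS groups (119 higher, 58 lower), and the latter fit was taken to decide after both values had been seen. The 177 genes argue against 1 fraction for themselves only, 28 of them interferon-stimulated genes that lay above it and 5 ERK targets and 5 cholesterol genes below it. A weaker block of the same pathway remains open, since doses are not given and the test covers only 1 fraction common to all genes. By list the median ratio among genes lowered by the TPL2 inhibitor was 60.4% for 15 ERK targets, 35.7% for 24 cytokine genes and 28.5% for 11 stress response genes. Unlike the 47.4%, which came from changes in different donors, these ratios use the same libraries that chose the genes. That choice can bias them, and no spread was computed, so they only describe the genes called.

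Interferon-stimulated genes lay higher under the MEK inhibitor and not under the TPL2 inhibitor, with summed levels of 5457 CPM in unstimulated cells, 7925 with LPS, 8260 with the TPL2 inhibitor and 11865 with the MEK inhibitor. Genes of like expression and donor spread did not move as this list did (median 0.52): 10000 random lists of them had a middle value of -0.02 and a highest of 0.08, and 0 of them reached 0.52 (0.01% with the list itself counted), which argues against a shift of variable genes in general. A scaling factor moves all genes of a library alike, and with library size alone the list lay 0.53 above the median of all other genes (0.01), which argues against scaling. Between the inhibitors edgeR called 1 of the 49 members lower with the TPL2 inhibitor in the fit of 20 libraries, DESeq2 7 and limma-voom 0. The fit of the 3 LPS groups called 32 of 48, and the list lost its camera call with an estimated correlation. As a hypothesis, MEK inhibition may raise this program in LPS-treated neutrophils. It remains open because the random lists do not carry the correlation between the members (0.682) and so leave a joint shift between donors open, edgeR called 0 of 49 members in the fit of 20 libraries (32 at an unadjusted p under 0.05; DESeq2 3, limma-voom 0) and 27 of 48 in that of the 3 LPS groups, the adjusted p of the list was 0.127 with an estimated correlation, and a response of the donors' cells to interferon was not tested.

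Leaving out the unstimulated libraries raised the calls for the MEK inhibitor from 86 to 542, while the biological coefficient of variation went from 11.2% to 6.95%. For each gene, the variance between donors of the LPS change was divided by the mean variance of the differences between the 3 LPS groups. The median of this variance ratio was 5.26 in 1337 genes called for LPS at 2-fold or more and 2.08 in 912 genes of like expression without a call for LPS. The ratio of both, 2.53, is what donors that differ in their LPS response would give. Noisier unstimulated libraries would raise the ratio in genes without a call too, but the 2.08 cannot decide this. The genes were picked by their lack of a call in the same libraries, and a wide donor spread of the LPS change itself prevents a call. Noisier unstimulated libraries remain open, and the parts of the 2 explanations were not separated.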
